A study of Danio rerio with 12 samples.

How the data were processed

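RNA-seq and whole-genome bisulfite sequencing libraries came from sorted zebrafish haemogenic endothelial cells, with 3 control and 3 dnmt3ba morphant samples per assay. Groups and replicate numbers were taken from the sample labels, and the design text states that replicates were biological. Per the submitters' processing notes, HISAT2 2.2.1, HTSeq 0.12.4, BS-Seeker2 2.1.8 and DESeq2 1.30.1 were used with the genome build GRCz11, without a role for each. The annotation, the strand setting, the region caller and the coverage minimum are not given in the sources used here.

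The expression table held, per the file headers, an estimated count, an FPKM value and a TPM value for each of 25011 genes in each library. The deposited estimated counts were whole for most genes, but 13.5 to 15.1% of values per library were not, and how these arose is not given in the sources used here. Of the genes named, these had counts that were not all whole: dnmt3aa, lmo2, stab2, itga3b, itgae.2, itgb1b.1, sycp1, ctnnb1, hbbe1.3, hbbe1.2, lcp1, actc1b, atp1a1a.4, hsp90aa1.2, kdrl and LOC100537178. The deposited TPM values have the same sum in each library, and the deposited counts divided by the deposited FPKM values give nearly the same length for a gene in each library (median coefficient of variation 0.51%). 19 gene symbols stand on 2 rows, and the first row kept the plain symbol. The methylation table held, per the file headers, a methylation fraction per group for each region, their difference, the number of CpG sites and an FDR, used here as the authors' deposited q-value, all under 0.05. Fractions are printed as percentages. Chromosome numbers were derived from the RefSeq sequence names, and 1268 regions lay on 644 unplaced scaffolds.

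Estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with the group, which left 18846, and were scaled by TMM. The main test was the edgeR 4.0.16 quasi-likelihood F-test of morphant against control with the group as the only term, in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Fold changes are morphant over control, and their SE was derived from the F statistic. CPM values are TMM-normalised. TMM factors ran from 0.932 to 1.11. Gene lists were tested with limma 3.58.1 on voom values, with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Adjustment was over the 22 lists with at least 3 tested genes. 23 lists were fixed, of which the mitochondrial genome list had 0 genes in the file. Members missing under their name were looked up by synonym in a RefSeq gene table of the assembly GRCz12tu, used for names alone. The lists overlap in places: spi1b, tal1, notch3, il1b and csf1ra each on a pair of lists.

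The lists, tests and most alternatives were chosen before the data were examined. The genes named are dnmt3ba; up to 12 rises and 12 falls, largest first, among called genes with a mean of at least 5 CPM, no overlap between groups and an established symbol; called integrins; and up to 4 called members of each other list, or its 2 most abundant members where none was called. A called gene and a gene list are not reported here. Others are said to have been chosen after their values were seen. For regions the rule took the 6 largest losses and 6 largest gains; its condition of a gene symbol could not be applied. The alternatives fixed beforehand were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter and a stricter filter (at least 5 CPM in 3 libraries), a minimum absolute log2 fold change of 1, a replicate block, leaving out each library, and for regions a stricter q, larger differences and more CpG sites. Added after seeing the data were an adjusted p under 0.10, leaving out control 2 and morphant 2 together, and a gene-length correction. For the last, each library's deviation from the gene's mean log2 CPM was fitted by loess (span 0.5) on the log2 length implied by the authors' counts and FPKM, and the fitted trend entered edgeR as an offset.

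The tests were run on 3 sets of simulated counts drawn from the means, depths and dispersions of these libraries. The same filter was applied to the simulated counts and kept 18303 genes in the first set. Over the 3 sets, the genes kept included 207 changed 2-fold, 186 4-fold and 187 8-fold. Changed genes that the filter removed do not enter the recovery. edgeR recovered 2.9% of 2-fold, 53.2% of 4-fold and 71.7% of 8-fold changes, and DESeq2 19.8%, 75.8% and 88.8%; 10 of 249 edgeR calls and 184 of 532 DESeq2 calls were false. A planted list of genes was called by camera in each of the 3 sets, and 0 of 66 tests of other lists were. These counts were simulated without correlation between genes, so they do not bear on false calls of lists whose genes vary together. No test of single regions was made, since the table holds the authors' comparison with no values per replicate. Replicates of a group differed well beyond counting noise (chi-square per degree of freedom from 37.8 to 194 between pairs), so none was counted as a repeat of another.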

Results

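Haemogenic endothelial cells are the endothelial cells of the embryonic dorsal aorta from which haematopoietic stem and progenitor cells arise. They were sorted from the trunk of zebrafish embryos at 36 hours post-fertilisation, as cells positive for both a kdrl-driven mCherry reporter, which marks endothelium, and a GFP reporter under a runx1 enhancer, which marks blood-forming endothelium. Embryos were either controls or morphants, that is, embryos injected with a morpholino (a synthetic antisense oligonucleotide that blocks translation or splicing of a transcript) against dnmt3ba, which encodes a de novo DNA methyltransferase. What the controls were injected with, if anything, is not given in the sources used here, so each difference between the groups includes any effect of injection that they did not share. About 5000 cells were collected per sample. RNA-seq and whole-genome bisulfite sequencing, which reads cytosine methylation, were each done on 3 biological replicates per group. The RNA table held 25011 genes, and total estimated counts ranged from 24397076 in control 1 to 25132656 in morphant 1. The methylation data analysed here were the authors' deposited table of 7550 regions that differed between morphants and controls at a q of 0.05, with a level per group and none per replicate. The series title places the study's interest in integrin signalling and in the formation of stem and progenitor cells.

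The first comparison was of the targeted gene itself. dnmt3ba (gene ID 321084) was read at 408, 672 and 603 CPM in morphants 1, 2 and 3 and at 493, 787 and 441 CPM in controls 1, 2 and 3. The group means were 561 ± 137 and 574 ± 186 CPM (SD, n = 3), a log2 fold change of -0.04 with an SE of 0.29 (edgeR quasi-likelihood test, adjusted p = 0.95). The difference was smaller than the spread between replicates. Because a morpholino that blocks translation, or that skips an exon, need not lower the read count of its target, this value does not check the labels in either direction. Without control 2 the log2 fold change was 0.25, and without morphant 1 it was 0.15.

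The next comparison asked which transcripts differed between morphant and control cells. mdm2 (gene ID 30637), a ubiquitin ligase, rose 4.96-fold from 27.7 ± 1.52 to 139 ± 6.06 CPM (SD, n = 3; edgeR adjusted p = 0.0056). cdkn1a (100151416), the cell cycle inhibitor p21, rose 5.37-fold from 19.6 ± 4.23 to 106 ± 10.2 CPM (adjusted p = 0.02). The largest rise among genes called over all genes, with a mean of at least 5 CPM and an established symbol, was in lnx1 (561226), a ubiquitin ligase, at 24.9-fold, from 5.81 ± 2.46 to 146 ± 8.88 CPM (log2 fold change 4.64, SE 0.36, adjusted p = 0.0094). bmb (559540) rose 7.52-fold and lyve1a (560618), a homologue of the lymphatic hyaluronan receptor, rose 6.87-fold. rgs5b (550519), a regulator of G protein signalling, rose 6.33-fold, tcima (541345) 3.94-fold, and plk2a (100148413), a polo-like kinase, 3.32-fold. Their adjusted p lay between 0.0056 and 0.039. col1a2 (336471), a chain of type I collagen, fell 3.41-fold from 331 ± 22.9 to 98.0 ± 18.8 CPM (log2 fold change -1.77, SE 0.20, adjusted p = 0.039). slc38a5a (100005797), an amino acid transporter, fell 3.02-fold from 54.2 ± 6.20 to 18.1 ± 0.222 CPM (log2 fold change -1.59, SE 0.18, adjusted p = 0.039). These 10 genes were named by a rule that required the morphant and control values not to overlap, which chance gives for 10% of unchanged genes.

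In all, edgeR's quasi-likelihood test called 10 genes higher and 2 lower in morphants among 18846 tested, at a Benjamini-Hochberg adjusted p under 0.05. Another riser, LOC100537178, had no established symbol, and its estimated counts were not all whole. At an unadjusted p under 0.05 there were 1429 genes higher and 1782 lower, against 942 in all expected by chance. DESeq2 called 595 genes higher and 631 lower, including the 12, and limma-voom called 9 and 3. In counts simulated from these libraries with known changes, 4.02% of edgeR's calls and 34.6% of DESeq2's were false, and edgeR recovered 2.9% of 2-fold, 53.2% of 4-fold and 71.7% of 8-fold changes. After the filter, those 3 simulated sets held 207 genes changed 2-fold, 186 4-fold and 187 8-fold, and the first set held 18303 genes in all. False shares and recovery depend on how many genes change, so these values do not give those of the real calls. The number of calls rested on single libraries. It was 0 without morphant 1, 0 without morphant 3, 0 without control 3 and 1 without control 1, with 1737, 1869, 3019 and 2908 genes at an unadjusted p under 0.05. It was 77 without control 2 and 30 without morphant 2. Control 2 stood apart from the other 5 libraries on the first principal component (37.9% of variance), and morphant 2 lay closer to controls 1 and 3 than morphants 1 and 3 did. Leaving out both of these, an alternative chosen after seeing the data, gave 490 genes higher and 869 lower, including the 12.

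**Figure D1:**
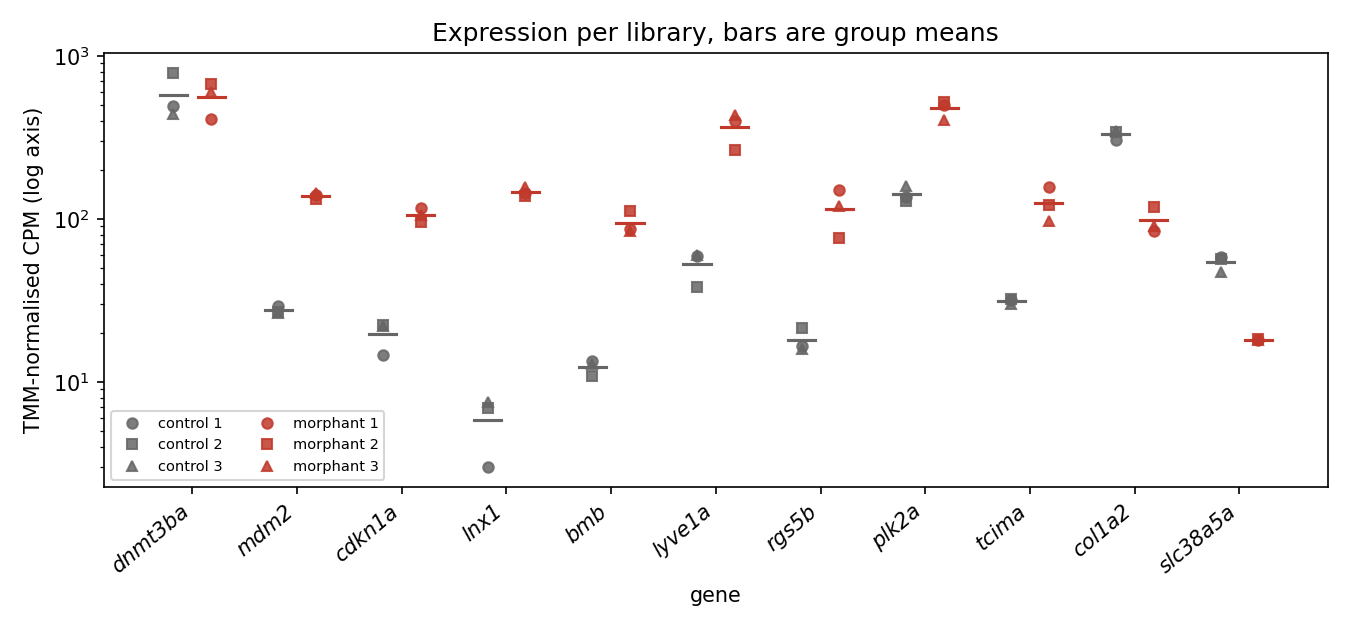
Expression per library in TMM-normalised CPM (log axis) of dnmt3ba and the 10 called genes named in the text with an established symbol. Grey points are the 3 control libraries, red points the 3 morphant libraries and bars the group means; mdm2 read 27.7 CPM in controls and 139 CPM in morphants, while the dnmt3ba values overlap.

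Of 27 pan-endothelial markers tested, 8 were higher in morphants and 0 lower when adjusted over the list alone, and 19 did not pass. None was called over all genes, and 25 had a positive log2 fold change. The list's median was 0.57, and limma's camera placed it above other genes (adjusted p = 1.8e-07 over 22 lists; adjusted p = 0.42 with an estimated correlation). Of the 12 lists called at the preset correlation of 0.01, 0 were called with an estimated correlation. The most abundant endothelial markers, plvapb and stab2, read 1560 ± 265 and 1130 ± 334 CPM in morphants and 807 ± 217 and 688 ± 122 CPM in controls (SD, n = 3). Of these, stab2 did not pass over the list alone. Named after their values were seen, etsrp, the early vascular regulator also called etv2, read 365 ± 30.0 CPM in morphants and 167 ± 62.8 in controls, and sox7 read 306 ± 65.5 and 146 ± 46.7 CPM. Those that did not pass included kdrl, the gene whose promoter drives the sorted reporter, at 520, 88.2 and 521 CPM in morphants 1 to 3 and 96.2, 183 and 74.4 CPM in controls 1 to 3. Adjusted over the list alone, 0 endothelial markers passed without morphant 1, 1 without morphant 3, 2 without control 1, 3 without morphant 2 and 12 without control 3. After a correction for gene length, chosen after seeing the data, 14 were higher and 1 lower (median 0.69), and without control 2 and morphant 2 it was 9 and 1 (median 0.33). Skeletal muscle markers had a median log2 fold change of -1.83 between the same libraries. Their mean was 9.41, 7.09 and 9.67 log2 CPM in controls 1 to 3 and 6.72, 7.88 and 6.86 in morphants 1 to 3. Control 2, whose muscle mean lay among the morphants, had the lowest endothelial mean, 6.99 log2 CPM.

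Among 24 tested regulators of haematopoietic stem and progenitor cells, 2 were higher and 3 lower when adjusted over the list alone, 19 did not pass, and none was called over all genes. The list as a set was not called (median log2 fold change -0.49, camera adjusted p = 0.13), though it was without morphant 1 (adjusted p = 0.048). Named after their values were seen, runx1 and myb, transcription factors needed for blood stem cell formation, were lower when adjusted over the list alone. runx1 read 13.7 ± 2.63 CPM in morphants and 32.1 ± 8.74 in controls (SD, n = 3; log2 fold change -1.25, SE 0.28), and myb read 231 ± 14.8 and 364 ± 2.39 CPM (log2 fold change -0.67, SE 0.15). Their adjusted p over all genes were 0.14 and 0.14 with edgeR and 0.0049 and 0.0022 with DESeq2. The repressor gfi1aa was lower, at 52.2 ± 8.38 against 104 ± 33.6 CPM, and its paralogue gfi1ab was higher, at 35.4 ± 11.4 against 12.7 ± 6.08 CPM. lmo2, the other riser of the list, read 380 ± 10.9 and 242 ± 30.5 CPM. cebpb, the most abundant member, read 3390 ± 423 and 2200 ± 503 CPM and did not pass. gata2b read 58.0 ± 13.3 and 67.2 ± 15.3 CPM. After a correction for gene length, chosen after seeing the data, the median was -0.32, with 0 higher and 2 lower when adjusted over the list alone. None passed over the list alone without control 1, morphant 1, morphant 2 or morphant 3, and the median was -0.2 without control 2. Without control 2 and morphant 2 the median of the list was 0.06, with 5 members higher and 7 lower when adjusted over the list alone. In the main comparison, erythroid markers had a median log2 fold change of -1.62, with 23 of 23 genes negative.

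Arterial and Notch pathway genes, which specify the aortic endothelium, were not called as a set (median 0.26, camera adjusted p = 0.089). Over the single libraries left out the median ran from 0.1 without control 2 (adjusted p = 0.42) to 0.38 without control 3 (0.021). The adjusted p was 0.35 without morphant 2 (median 0.11) and 0.017 without morphant 1. With the same correction for gene length the list was called (median 0.37, adjusted p = 0.0023). Of 25 tested, 2 were higher and 0 lower when adjusted over the list alone. These were the tight junction gene cldn5b, at 349 ± 42.5 CPM in morphants and 135 ± 38.1 in controls (SD, n = 3), and the Notch ligand dlc, at 129 ± 25.8 and 52.8 ± 13.8 CPM. The most abundant members, her9 and her6, read 568 ± 75.7 and 453 ± 126 CPM in morphants and 418 ± 229 and 372 ± 195 CPM in controls, differences within the spread of the replicates.

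Integrins, the receptors that bind cells to matrix and are named in the series title, showed no call over all genes by edgeR. Adjusted over the list alone, 0 were higher and 2 lower of 26 tested, with 24 that did not pass. At an unadjusted p under 0.05 there were 10, chosen here after their values were seen. The 2 that passed were itgb1a, a beta 1 integrin subunit, at 3.52 ± 0.879 CPM in morphants and 11.2 ± 0.928 in controls (SD, n = 3), and itga3b, at 1.33 ± 0.787 and 6.97 ± 2.44 CPM. Their log2 fold changes were -1.68 (SE 0.30) and -2.40 (SE 0.54), with edgeR adjusted p over all genes of 0.11 and 0.14 and DESeq2 adjusted p of 6.1e-05 and 0.0012. The other 8 were itga6a (log2 fold change -0.95), itga7 (-2.43), itga8 (-1.07), itgae.2 (-0.70), itgb1b.1 (-1.61), itgb4 (-2.08), itgb3b (1.44) and itgb5 (0.62). In 3 of these control 2 lay far above the other libraries: itgb1b.1 read 5.82, 20.7 and 4.96 CPM in controls 1 to 3, itga8 12.7, 28.5 and 9.79 CPM and itgae.2 58, 113 and 64 CPM. Without control 2 and morphant 2 their log2 fold changes were -0.33, -0.41 and -0.24. Skeletal muscle (median -1.83) and epidermal (-1.33) markers were lower as sets between the same libraries by camera at the preset correlation. With an estimated correlation neither was called (camera adjusted p = 0.42 and 0.56). In itga7 (2.97 CPM) and itgb4 (4.56 CPM) control 2 lay among the morphants, as it did for muscle genes such as actc1b. DESeq2 called 1 integrin higher, itgb3b, and 4 lower. As a set the integrins were not separated from other genes (median -0.28, camera adjusted p = 0.17). By limma's fry, which asks whether the genes of a set move on balance in a single direction and does not compare them with other genes, they were lower (fry adjusted p = 0.039 over the lists). Without control 2 the median was 0.03 with 5 lower when adjusted over the list alone, and 0 passed without control 3 or without morphant 2. Without control 2 and morphant 2 together, 1 integrin was higher and 7 lower over the list alone (median -0.28). After a correction for gene length, chosen after seeing the data, the median was -0.08 and 0 integrins passed over the list alone. Of 48 focal adhesion and integrin signalling genes, 0 were higher and 0 lower when adjusted over the list alone (median -0.03, camera adjusted p = 0.62). The most abundant of these were actn4, at 561 ± 50.4 CPM in morphants and 782 ± 114 in controls, and cdc42, at 624 ± 28.1 and 476 ± 6.89 CPM.

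Of 32 tested genes of the extracellular matrix, to which integrins bind, 13 were lower and 1 higher when adjusted over the list alone, with 18 that did not pass. col1a2 was called over all genes, and 26 of the 32 had a negative log2 fold change. The median was -0.67 (camera adjusted p = 8e-06; adjusted p = 0.42 with an estimated correlation). Named after their values were seen, col1a1a read 57.3 ± 14.3 CPM in morphants and 296 ± 87.0 in controls (SD, n = 3), and the matrix glycoprotein gene thbs1a read 5.05 ± 2.60 and 39.0 ± 5.25 CPM. The fibronectin gene fn1b read 5.12 ± 3.6 and 42.1 ± 34.9 CPM. The riser was col4a2, a collagen of basement membranes, at 58.4 ± 12.9 and 18.8 ± 5.97 CPM. Skeletal muscle markers had a median of -1.83 between the same libraries. The notochord, sclerotome and mesenchyme list was not called (median -0.98, camera adjusted p = 0.27), with 13 fold changes negative and 7 positive. Without control 2 and morphant 2 that list was called lower (median -1.13, camera adjusted p = 0.0039). Fold changes were related to gene length across 18824 genes, which are not independent replicates (Spearman's rho = -0.28), with longer genes lower in morphants. After the correction for length the median of the matrix genes was -0.28 (camera adjusted p = 0.0071), with 8 lower and 3 higher when adjusted over the list alone. Without control 1 or morphant 1, 5 were lower when adjusted over the list alone, without control 3 it was 6 and without morphant 3 it was 8. Without control 2 and morphant 2 the median was -1.06.

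Of 21 tested transcripts of the DNA methylation machinery, 4 were lower and 0 higher when adjusted over the list alone, 17 did not pass and none was called over all genes. A negative log2 fold change was found in 18, or 17 of 20 without dnmt3ba (median -0.52, camera adjusted p = 0.003; adjusted p = 0.42 with an estimated correlation). dnmt3bb.1, the most abundant of the list besides dnmt3ba and a de novo methyltransferase, read 311 ± 3.35 CPM in morphants and 555 ± 156 in controls (SD, n = 3). Named after their values were seen, the other 3 were the maintenance methyltransferase dnmt1, at 50.6 ± 5.74 and 109 ± 32.0 CPM, its partner uhrf1, at 43.3 ± 5.25 and 120 ± 73.1 CPM, and dnmt3aa, at 10.9 ± 1.51 and 27.7 ± 4.80 CPM. DESeq2 also called these 4 lower. Control 2 was the highest control for dnmt3bb.1 (424, 727 and 514 CPM in controls 1 to 3), dnmt1 (81.5, 144 and 101) and uhrf1 (84.5, 204 and 71.3). It was the lowest for dnmt3aa (30, 22.2 and 30.9). The log2 fold changes of dnmt3bb.1, dnmt1 and uhrf1 were -0.85, -1.12 and -1.48, and their smallest falls over the alternatives were -0.61, -0.74 and -0.86. After the correction for gene length the median was -0.17 (camera adjusted p = 0.083), with 1 lower and 1 higher when adjusted over the list alone. None passed over the list alone without morphant 1 or morphant 3, and 8 did without control 1. Without control 2 the median was -0.23, and without control 2 and morphant 2 it was -0.3. Cell cycle genes had negative fold changes in 28 of 32 (median -0.47, camera adjusted p = 2.6e-07; adjusted p = 0.42 with an estimated correlation). Adjusted over the list alone, 1 was lower, top2a, at 75 ± 10.4 and 169 ± 43.0 CPM. The most abundant, pcna and mcm2, read 665 ± 100 and 358 ± 53.3 CPM in morphants and 880 ± 138 and 538 ± 154 CPM in controls and did not pass. Control 2 had the highest mean of the cell cycle genes, 6.88 log2 CPM, and without control 2 and morphant 2 the median was -0.26 (camera adjusted p = 0.0038). Skeletal muscle markers had a median of -1.83 and erythroid markers of -1.62 between the same libraries.

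**Figure D2:**
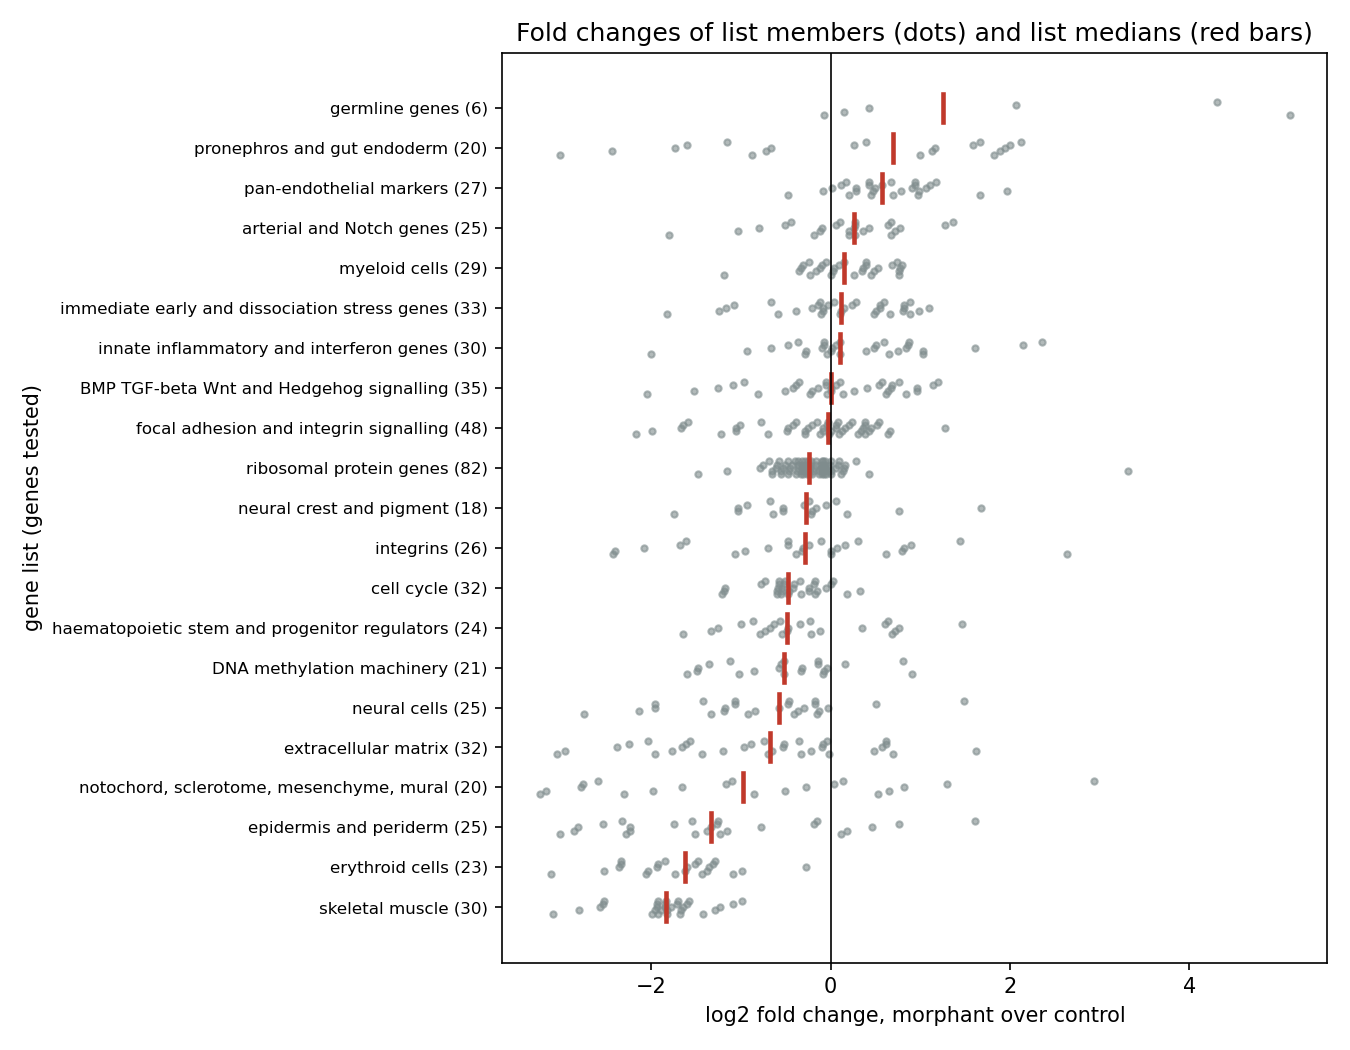
Log2 fold change (morphant over control) of each tested member of the gene lists reported. Each grey dot is a gene, red bars are list medians and the number of tested genes is in parentheses; the pan-endothelial list has a median of 0.57 and the skeletal muscle list a median of -1.83.

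Genes of the BMP, TGF-beta, Wnt and Hedgehog pathways moved in both directions. Of 35 tested, 6 were higher and 1 lower when adjusted over the list alone, with a median of 0.01 (camera adjusted p = 0.089). The median was 0.17 without control 3 (adjusted p = 0.014) and 0.18 without morphant 1 (0.021), against -0.03 without control 2 (0.55) and -0.11 without morphant 2 (0.35). The risers, named after their values were seen, were the receptor genes acvrl1 (log2 fold change 1.14) and tgfbr2b (0.96), the ligand bmp6 (0.96), and smad1 (0.64), smad5 (0.84) and smad6b (1.2), which encode intracellular parts of BMP signalling. The ligand tgfb3 (-2.05) was lower. ctnnb1, the most abundant member, read 575 ± 49.8 CPM in morphants and 585 ± 111 in controls (SD, n = 3), and tgfbr2b read 393 ± 17.6 and 201 ± 66.4 CPM. Innate, inflammatory and interferon genes were not called as a set (median 0.11, camera adjusted p = 0.055). Over the single libraries left out the median ran from -0.01 without morphant 1 (adjusted p = 0.22) to 0.46 without control 2 (0.021). The adjusted p was 0.021 without control 1, 0.0029 without morphant 2 and 0.27 without control 3 (median 0.06). Of 30 tested, 3 were higher and 0 lower when adjusted over the list alone. They were socs3a, at 1310 ± 216 and 633 ± 168 CPM, socs3b, at 937 ± 107 and 510 ± 60.2 CPM, and the interferon-stimulated gene isg15, at 18.1 ± 3.65 and 3.50 ± 0.489 CPM.

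Immediate early and dissociation stress genes, which respond within minutes to handling of cells, were higher as a set (median 0.12, camera adjusted p = 0.021; adjusted p = 0.42 with an estimated correlation). The call was lost without control 1 (adjusted p = 0.1), without morphant 2 (0.091) and with the stricter filter (0.056). The median was 0.35 without control 2, 0.23 without morphant 2 and 0.07 without morphant 3. Of 33 tested, 19 had a positive log2 fold change and 14 a negative one. Adjusted over the list alone, 5 were higher and 1 lower. Named after their values were seen, the 5 were the transcription factor genes jun (log2 fold change 0.98), junba (0.89), fosab (0.82) and atf3 (0.81) and the phosphatase gene dusp1 (1.1), and the chaperone gene hsp90aa1.2 (-1.82) was the member that was lower. fosab and junbb, the most abundant, read 4670 ± 668 and 3510 ± 443 CPM in morphants and 2630 ± 484 and 2390 ± 571 CPM in controls (SD, n = 3), and junbb did not pass over the list alone. Of the germline list only 6 genes were tested, with 2 higher and 0 lower when adjusted over the list alone (median 1.25, camera adjusted p = 0.034; adjusted p = 0.42 with an estimated correlation). The call was lost without control 1 (adjusted p = 0.1), control 3 (0.087) or morphant 2 (0.09). By fry the germline genes were higher (fry adjusted p = 0.007), and the lowest fry adjusted p of the other lists reported, besides the integrins, was 0.091. The risers lay near the floor of detection in controls: tdrd9 read 2.05, 1.54 and 2.73 CPM in morphants and 0.0856, 0 and 0.0855 CPM in controls, and ddx4 read 2.49, 0.711 and 1.28 CPM and 0.214, 0 and 0 CPM. The most abundant, tdrd5 and sycp1, read 1.82 ± 1.37 and 1.33 ± 0.290 CPM in morphants and 1.35 ± 0.504 and 1.18 ± 0.396 CPM in controls. Ribosomal protein genes had a median of -0.24 over 82 genes (camera adjusted p = 0.048; adjusted p = 0.82 with an estimated correlation), a call that was lost on leaving out morphant 1 (0.26) or morphant 2 (0.066). The median was further below other genes without control 2 (-0.53, camera adjusted p = 2.2e-23) and after the gene-length correction (-0.37, camera adjusted p = 3.2e-13). Both p-values are at the preset correlation. These genes varied together (estimated correlation 0.9 in the main comparison), so they overstate the evidence. Without control 1 or control 3 the set lay above other genes, without a call (adjusted p = 0.69 and 0.91). rps27l, at 727 ± 88.2 and 72.4 ± 38.4 CPM (SD, n = 3), was the 1 member that passed over the list alone. rpl3 and rps2 read 2440 ± 251 and 2700 ± 307 CPM in morphants and 4170 ± 757 and 3320 ± 761 CPM in controls.

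Markers of other trunk cell types were measured in the same libraries. Skeletal muscle markers had a negative fold change for 30 of 30 genes (median -1.83, camera adjusted p = 1.6e-10; adjusted p = 0.42 with an estimated correlation), and 6 were lower and 24 did not pass when adjusted over the list alone. The alpha-actin gene actc1b read 5280, 9820 and 4440 CPM in morphants 1 to 3 and 22500, 5370 and 34400 CPM in controls 1 to 3, so that control 2 lay among the morphants. The myosin light chain gene mylpfa read 1260 ± 461 and 4400 ± 3370 CPM (SD, n = 3). Both were among the muscle genes that did not pass over the list alone, and the estimated counts of actc1b were not all whole. Erythroid markers had a negative fold change for 23 of 23 genes (median -1.62, camera adjusted p = 6.1e-09; adjusted p = 0.42 with an estimated correlation), and 8 were lower and 15 did not pass when adjusted over the list alone. The globin genes hbbe1.3 and hbbe1.2, whose estimated counts were not all whole, read 525 ± 316 and 393 ± 240 CPM in morphants and 1320 ± 734 and 950 ± 463 CPM in controls. alas2, a gene of haem synthesis named after its values were seen, read 18.4 ± 8.51 and 91.9 ± 66.8 CPM. Without control 1 the erythroid median was -0.82, with 22 of 23 genes negative. Adjusted over the list alone, the erythroid markers lower were 0 without morphant 3, 1 without morphant 2, 3 without control 1 and 20 without control 2, and the muscle markers lower were 28 without control 2 and 24 without morphant 2.

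Neural markers (25 tested, median -0.57, camera adjusted p = 0.00018; adjusted p = 0.42 with an estimated correlation) and epidermal markers (25 tested, median -1.33, camera adjusted p = 0.017; adjusted p = 0.56 with an estimated correlation) were lower as sets, with 0 members of either passing over the list alone. The epidermal call was lost without control 1 (adjusted p = 0.22), without morphant 2 (0.097), without control 2 and morphant 2 (0.27) and with the stricter filter (median -0.82, adjusted p = 0.11), and the epidermal median was -0.72 without control 2. The neural median was -1.02 without morphant 2 and -0.36 without morphant 3. The most abundant neural genes, tubb5 and rtn1a, read 56.2 ± 21.9 and 59.9 ± 8.52 CPM in morphants and 76.7 ± 12.6 and 65.0 ± 22.5 CPM in controls (SD, n = 3). The most abundant epidermal genes, krt18a.1 and pfn1, read 3450 ± 347 and 3340 ± 1520 CPM in morphants and 3800 ± 1980 and 2910 ± 530 CPM in controls. The notochord, sclerotome, fin mesenchyme and mural list was not called (20 tested, median -0.98, camera adjusted p = 0.27). Its median was -0.53 without morphant 3, -0.63 without control 3, -0.62 with the replicate block and -2.02 with the stricter filter (adjusted p = 0.19). It was called lower without control 2 and morphant 2 (median -1.13, adjusted p = 0.0039). Its most abundant gene, the cartilage and notochord collagen col2a1a, read 192, 1230 and 140 CPM in morphants and 5350, 2500 and 6180 CPM in controls, and tagln2 read 819 ± 126 and 518 ± 191 CPM. Myeloid genes varied together (estimated correlation 0.79 in the main comparison), so camera at the preset correlation overstates the evidence for a shift of their list. Myeloid markers were not called (29 tested, median 0.15, camera adjusted p = 0.44). They were higher in morphants without control 2 (adjusted p = 0.008) or without morphant 2 (0.00052), and camera placed them below other genes, without a call, on leaving out control 3 (0.23), morphant 1 (1) or morphant 3 (0.31). The lysozyme gene lyz read 4130 ± 2750 and 3200 ± 1220 CPM, and lcp1 read 1490 ± 749 and 1440 ± 698 CPM. Pronephros and gut markers (20 tested, median 0.70, camera adjusted p = 0.5, and 0.037 without morphant 2) included the tubule genes atp1a1a.4, at 832 ± 780 and 234 ± 195 CPM, and cdh17, at 515 ± 497 and 132 ± 91.2 CPM. Neural crest and pigment markers (18 tested, median -0.27, camera adjusted p = 0.83) included paics, at 45.5 ± 4 and 52.0 ± 5.24 CPM, and tyrp1b, at 25.2 ± 17.6 and 29.1 ± 24.4 CPM. No member of these last 4 lists passed over the list alone.

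The remaining comparison was of DNA methylation. In the authors' deposited table, 6807 of 7550 regions (90.2%) had a lower methylation level in morphants than in controls and 743 (9.84%) a higher level. The split departed from equal numbers by a two-sided exact binomial test (p at most 1e-300), although regions are not independent replicates and the table holds only regions past the authors' filter. The smallest difference in the authors' deposited table was 10 percentage points and the fewest CpG sites per region 5. Regions that were lower had a median level of 61.0% in controls and 30.9% in morphants in the authors' deposited table, a median difference of -23.0 percentage points, over a median of 13 CpG sites and 236 bp. Of these, 2355 (34.6%) ended under 20% methylation in morphants. Regions that were higher went from a median of 67.5% in controls to 86.7% in morphants in the authors' deposited table, a median difference of 16.1 percentage points, over a median of 10 CpG sites and 133 bp. The loss was present on each of the 25 chromosomes, where the share of higher regions ran from 6.29% on chromosome 24 to 15.8% on chromosome 22 in the authors' deposited table. Among the 512 regions that differed by at least 40 percentage points in the authors' deposited table, 508 were lower and 4 higher. The coverage behind each level is unknown here, and no replicate values were used, so these levels carry no error. In the RNA libraries of the same comparison, skeletal muscle markers had a median log2 fold change of -1.83. Whether the mix of cells differed between the bisulfite samples was not tested.

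**Figure D3:**
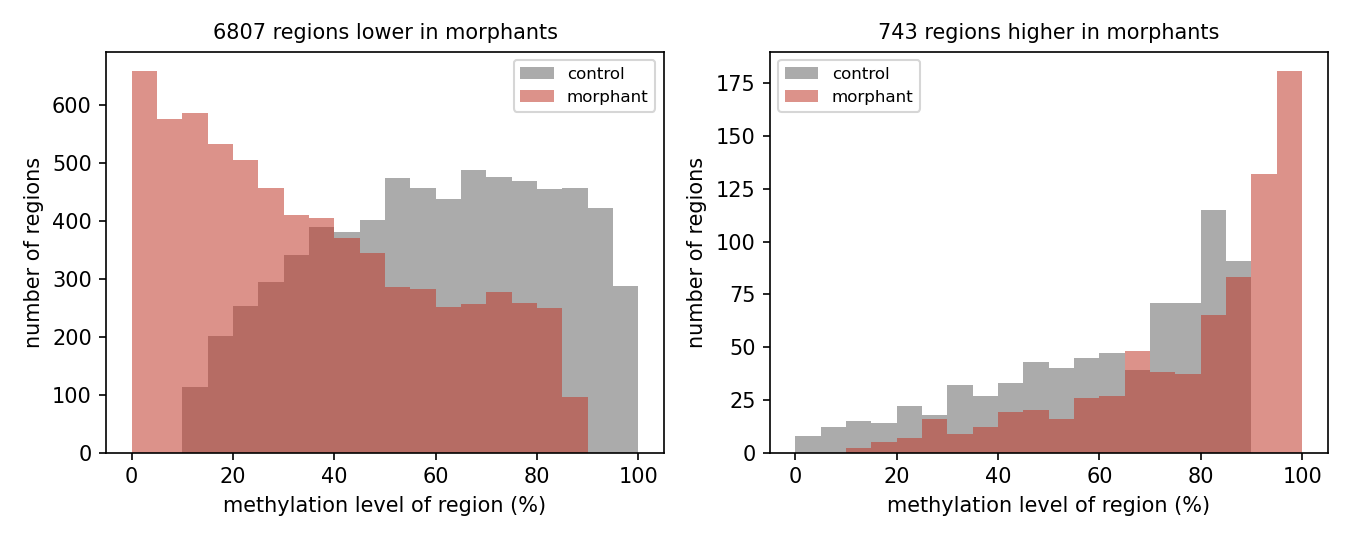
Number of regions of the authors' deposited table by methylation level (%) in controls (grey) and morphants (red), in bins of 5 percentage points. The left panel holds the 6807 regions that were lower in morphants, whose median moved from 61.0% to 30.9%, and the right panel the 743 that were higher, whose median moved from 67.5% to 86.7%.

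Single regions are given by GRCz11 coordinates as in the authors' deposited table, which carries no gene names. Whether the start counts from 0 or 1 is not given in the sources used here. The largest loss in the authors' deposited table was on chromosome 7 from 54157041 to 54157118, where 5 CpG sites went from 93.2% in controls to 12.7% in morphants (authors' q = 0.0033). On chromosome 23 from 40818134 to 40818369, 14 sites went from 80.7% to 13% in the authors' deposited table (q = 9.7e-09). Further losses of over 60 percentage points in the authors' deposited table were on chromosome 8 from 33716213 to 33716266 (79.4% to 12.6%) and from 6990219 to 6990577 (82.2% to 19.5%), on chromosome 3 from 54916809 to 54917074 (91.4% to 28.9%) and on chromosome 24 from 278412 to 278468 (67.7% to 5.62%). The largest gain in the authors' deposited table was on chromosome 10 from 27387545 to 27387634, where 5 sites went from 25.4% to 78.9% (q = 0.0068). Gains also stood on chromosome 2 from 42242040 to 42242197 (35.7% to 79.0%) and on chromosome 1 from 57581356 to 57581523 (42.9% to 83.4%) and from 34433440 to 34433573 (51.4% to 91.1%) in the authors' deposited table. The other 2 of the 6 largest gains in the authors' deposited table were on chromosome 5 from 72145510 to 72145602 (44.5% to 84.7%) and on chromosome 11 from 43571132 to 43571181 (51.2% to 90.7%). Of these losses and gains, only that on chromosome 23 held more than 13 CpG sites, the median of the authors' deposited table. The highest authors' q among them were 0.047 on chromosome 1 from 34433440 (5 sites), 0.015 on chromosome 11 (6 sites) and 0.014 on chromosome 24 (5 sites). Genes were not assigned to regions, because the annotation at hand was of another build, so the relation of methylation to expression was not analysed here.

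Some of the 743 gains of methylation lay in runs of neighbouring regions. Among successive regions at most 10000 bp apart in the authors' deposited table, there were 23 pairs with both regions higher. The longest run in the authors' deposited table was 7 regions on chromosome 7, from 4247109 to 4271315, a span of 24206 bp with 485 CpG sites, in which gains ran from 22 to 36.2 percentage points. Its region with the most sites, from 4257270 to 4263318, held 224 and went from 64.7% in controls to 89.5% in morphants in the authors' deposited table. A run of 6 regions on chromosome 15, from 14232580 to 14244692, held 519 sites, with levels of 51.6 to 67.5% in controls and 88.2 to 93% in morphants in the authors' deposited table.

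**Figure D4:**
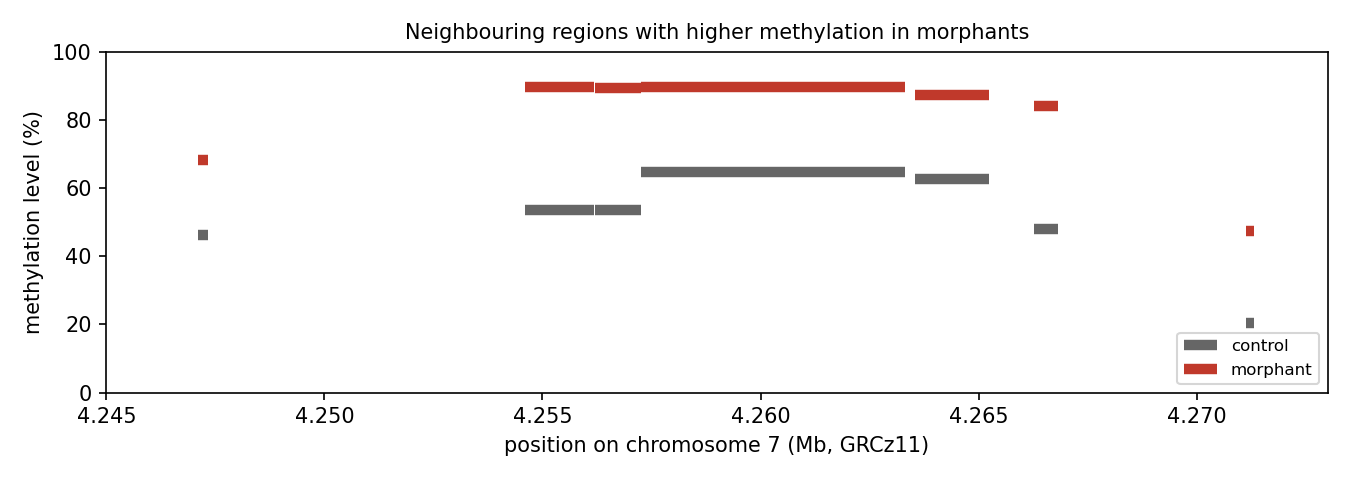
Methylation level (%) in controls (grey) and morphants (red) of the 7 regions of the run on chromosome 7 (GRCz11) in the authors' deposited table, each drawn from its start to its end. The regions from 4247109 to 4271315 lie higher in morphants, by 22 to 36.2 percentage points.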

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

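Tests chosen after the results were seen are the adjusted p under 0.10, leaving out control 2 and morphant 2 together, and the gene-length correction. The main comparison called 10 genes higher and 2 lower. RLE and upper-quartile scaling, and a minimum absolute log2 fold change of 1, gave the same counts, limma-voom gave 9 and 3, and the stricter filter 12 and 3. DESeq2 gave 595 higher and 631 lower, no filter 29 and 8, the replicate block 0 and 0 (2517 genes at an unadjusted p under 0.05), the adjusted p under 0.10 61 and 23, the gene-length correction 33 and 5, and leaving out control 2 and morphant 2 together 490 and 869. Leaving out single libraries gave 0 to 31 higher and 0 to 46 lower. The labels state no pairing of morphants with controls. Libraries of the same number did not deviate from their group means alike (correlation across genes 0.03, -0.09 and -0.16 for numbers 1 to 3). A looser threshold calls more by construction. Otherwise the cause was not tested. The 12 gene lists called at the preset correlation became 0 with the estimated one. For single lists, the replicate block ended the ribosomal call (adjusted p = 0.078) and gave calls to the arterial (0.048) and innate (0.042) lists. Leaving out control 2 and morphant 2 together ended the germline call (0.07) and gave calls to the innate (0.001) and notochord (0.0039) lists. Of the values for named genes and lists, 1747 kept their direction and side of the threshold, 92 lost a call, 176 gained one and 42 reversed.

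dnmt3ba ran from -0.2 to 0.25 over the libraries left out, and was 0.1 without control 2 and morphant 2 and 0.32 with the gene-length correction. The reversed log2 fold changes below belong to genes without a call; the cause was not tested. With the gene-length correction they were 0.11 for ctnnb1, -0.04 for lyz, -0.01 for lcp1 and -0.04 for pfn1. With limma-voom they were -0.02 for lcp1, 0.03 for krt18a.1 and 0.68 for tyrp1b, with the stricter filter -0.01 for lcp1, and with the replicate block 0.01 for krt18a.1 and 0 for tyrp1b. Without control 2 and morphant 2, tdrd5 was -0.27. Over the libraries left out they ran from -0.07 to 0.69 for her6, -0.39 to 0.77 for tdrd5, -0.09 to 0.33 for sycp1, -0.18 to 0.08 for ctnnb1, -0.31 to 0.7 for lyz, -0.32 to 0.49 for lcp1, -0.39 to 0.03 for rtn1a, -0.53 to 0.09 for krt18a.1, -0.09 to 0.51 for pfn1, -0.78 to 0.28 for tyrp1b.

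The direction of these lists against other genes also reversed without a call, and the cause was not tested. Their medians over the libraries left out ran from -0.14 to 0.05 for focal adhesion and integrin signalling, -0.21 to 0.6 for myeloid cells, 0.29 to 1.03 for pronephros and gut endoderm, -0.59 to -0.07 for neural crest and pigment, -0.53 to -0.03 for ribosomal protein genes. With the gene-length correction focal adhesion and integrin signalling had 0.07, and without control 2 and morphant 2 BMP TGF-beta Wnt and Hedgehog signalling had -0.05. The values of 6807 regions lower and 743 higher in the authors' deposited table became 4542 and 326 at a q under 0.01, 2877 and 105 at a difference of at least 25 percentage points, 508 and 4 at 40, and 3641 and 258 with at least 13 CpG sites. These alternatives keep fewer regions by construction, and each kept the direction. Depth behind the methylation levels is unknown. Not run were a pseudocount or filter on normalised values, since counts were used, coverage and replicate alternatives for regions, which had no such values, and regions with a gene, with every result on their overlap, direction or relation with expression, since no annotation of the build was at hand.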

Other observations

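The tests in this part were chosen after the results were seen, except the splits of the libraries. Some of the 743 methylation gains formed runs of neighbouring regions in the authors' deposited table. Among 1814 pairs of successive regions at most 10000 bp apart, a region that was higher in morphants was followed by another higher region in 35.9% of 64 cases, and a region that was lower was followed by a higher one in 2.74%. Shuffling directions within each sequence 1000 times gave a median of 10% and at most 18% after a higher region (permutation p = 0.001, the smallest these shuffles can give). Of the 23 pairs with both regions higher, 11 lay in the longest 2 runs and 15 were at most 1000 bp apart, so a few stretches that the table splits into pieces carry much of this share. The longest run of higher regions was 7 in the authors' deposited table and at most 6 in the shuffles.

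The densest stretch of change in the authors' deposited table lay on chromosome 15. Between 9 and 10 Mb there were 37 regions, 36 of them lower in morphants, against a median of 4 regions per 1-Mb bin over the 1300 bins with a region. Their median level was 36.0% in controls and 17.7% in morphants in the authors' deposited table. The region with the most CpG sites in the authors' deposited table, 228 on chromosome 4 from 77557471 to 77559387, went from 75.9% to 54.9%. A region of the same length and number of sites on an unplaced scaffold went from 76.2% to 55%.

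The real split of the 6 RNA libraries gave 12 called genes with edgeR, and the other splits into 3 and 3 gave at most 0; as large a count came from 1 of the 10 splits, the real one. DESeq2 called 1226 genes in the real split, 743 with morphant 1, morphant 3 and control 2 on a side and 119 with morphant 1, morphant 3 and control 1. In the remaining splits it called from 0 to 29. Each mixed split still keeps 2 morphants together on a side. Whether its calls there follow the groups or other differences between libraries therefore cannot be told apart. For the gene lists, the real split gave 12 calls with camera at the preset correlation and the highest other split 14, and 2 of 10 splits gave as many, the real one included. The 10 splits are too few for a share under 0.05.

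The matrix and DNA methylation lists were lower in morphants at the preset correlation (adjusted p = 0.42 for both with an estimated correlation), while the integrins were not called (adjusted p = 0.17). Libraries differed in a trend with gene length: the correlation of a library's deviations with length across genes was -0.31, 0 and -0.21 in morphants 1 to 3 and 0.06, 0.29 and 0.05 in controls 1 to 3. After removing that trend, the median over the 78 genes of these 3 lists went from -0.43 to -0.12, so the trend with gene length between the libraries may account for much of the shift of these lists. Of the 13 matrix genes that were lower when adjusted over the list alone, 8 stayed so after the gene-length correction. For these 8 genes, that argues against the trend as the only source of their fall. For the rest of the 13 the trend stays open as a source. The corrected fit also called more genes over all genes, 38 against 12, so passing it was not a stricter test. RNA of other matrix-making tissues, an effect of the knockdown on long genes and what gave the libraries their trend were not tested and stay open.

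Muscle, erythroid, epidermal and neural marker lists were lower in morphants by camera at the preset correlation. The cells were sorted for 2 reporters that mark endothelium and blood-forming endothelium. Muscle RNA was still read in each library: actc1b at 5280, 9820 and 4440 CPM in morphants 1 to 3 and 22500, 5370 and 34400 CPM in controls 1 to 3. kdrl read 520, 88.2 and 521 CPM and 96.2, 183 and 74.4 CPM in the same order. The sorts thus did not exclude muscle RNA in either group, while the share of cells of these types was not measured. With an estimated correlation none of these marker lists was called (adjusted p = 0.42, 0.42, 0.56 and 0.42), and 0 epidermal and 0 neural markers passed over the list alone. Myeloid markers had a median of 0.15 (adjusted p = 0.44). Without control 2 and morphant 2 it was 0.87, against -2.72 for muscle. The myeloid camera adjusted p there was 2e-08 at the preset correlation. It overstates the evidence, since the genes of each list varied together (estimated correlation 0.79 for myeloid and 0.89 for muscle in the main comparison). The 2 medians differ in direction, but they rest on libraries left out after their values were seen. They therefore do not decide whether the loss was uniform. Whether the morphant sorts held fewer unwanted cells of every type cannot be told apart from a loss of particular types: the muscle score minus the myeloid score differed by -1.75 log2 units (SE 1.41) between the groups, and the groups overlap. A smaller muscle or erythroid compartment in the morphants stays open and untested.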
